A study of Mus musculus with 24 samples.

How the data were processed

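RNA sequencing was carried out on mice lacking Cmtr2, a methyltransferase that modifies the cap structure at the 5′ end of mRNAs, and on their wild-type littermates. The series holds 24 libraries in 3 sets: embryos at embryonic day 8.5 (E8.5), embryos at E9.5 and yolk sacs at E9.5. Each set has 4 knockout (KO) and 4 wild-type (WT) libraries. Per the series' own description, the E8.5 embryos came from 2 litters and the E9.5 samples from 4. The litter of each library is not given in the sources used here. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase and made into libraries with an NEBNext Ultra kit by a sequencing service. The sources do not state that the counting used strand, so reads of overlapping antisense genes cannot be told apart.

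The values are FPKM (fragments scaled by gene length and by library size) per gene, deposited by the authors as 1 table per set. Per the submitters' processing notes, DESeq2 and the genome builds GRCm38 and mm10 were used, and the aligner and counter are not given in the sources used here. Each of the 3 tables lists 54532 gene IDs, of which 54495 are in the GENCODE M21 annotation that supplied gene symbols, positions and lengths. Low FPKM values were whole multiples of the value of 1 fragment when divided by gene length. At a tolerance of 0.02 fragments, between 96.6 and 97.9 percent of the low values of each library came out whole, which gave depths of 15555422 to 23373128 fragments per library. The lengths that did so were mean transcript lengths in the E8.5 table and the union of exons in both E9.5 tables. Levels are therefore not compared between the E8.5 table and the others, except on the stage axis, which used the recovered fragments. Each effect of genotype was estimated within 1 table.

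Libraries were grouped by their titles. The genotype tag was opposite to the title in 24 of 24 libraries, and the Cmtr2 level of each library went with its title. No 2 replicates were near-identical: Pearson correlations between replicates of a group, across genes, ran from 0.914 to 0.978. The labels do not say how the replicates of a group are related beyond litter, so p-values measure the spread between these samples.

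FPKM values were scaled by median-of-ratios factors within each table, a pseudocount of 0.5 was added and log2 was taken, so a fold change understates the change of genes with low FPKM. Genes with an FPKM of at least 1 in at least 4 of the 8 libraries were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, genotype as the only term). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All log2 fold changes are KO minus WT, with the standard error (SE) from limma. Differences of the genotype effect between stages and between tissues were tested as interaction contrasts in joint fits of 16 libraries. The E9.5 embryo and yolk sac libraries may come from the same conceptuses, and the joint fit treated them as independent. Cmtr2 was tested by an exact two-sided permutation test in each set. Lists of genes, 35 in all, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera was also run with the correlation estimated for each list, and the fry rotation test was run beside it. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

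The grouping, tests, gene lists, a set of alternatives and the rule for naming genes were fixed before the data were examined. The rule named Cmtr2 and its paralogue Cmtr1. For each comparison it named up to 8 risen and 8 fallen genes with the largest log2 fold change among called genes that have a standard symbol, a mean FPKM of at least 2 and no overlap between the groups. It also named up to 2 risen and 2 fallen members of each called list and of 4 lists that were always covered, up to 4 genes with the smallest p in each direction of each interaction, and a fixed panel of tissue, stage and stress genes. The result of 1 gene that the rule named is not reported here.

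The alternatives changed the pseudocount, the filter, the scaling, the empirical Bayes trend and the weights, added the replicate number as a block or embryo sex as a covariate, or left out each library in turn. Sex was read from Y-linked genes, which had an FPKM of 0 in E9.5 embryo WT replicate 4, where Xist was low as well (0.273). Voom on the recovered fragments, protein-coding genes alone, removal of a gene length trend, replicates 1 and 2 against 3 and 4 as a term or each pair of numbers alone, the omission of 3 E9.5 embryo libraries low in tail genes, the omission of WT replicate 1 in the E9.5 embryo list tests, quantile normalization of 3 of these list tests with and without the length trend, the omission of libraries on the stage axis and the list tests of the differences were added after the data had been seen. The fits of each set, the interactions and the list test were tested on simulated data, drawn as negative binomial fragment counts from the real means, library sizes and typical dispersion. Of genes changed 2-fold, the fit recovered 82.0 percent for E8.5 embryos (11795 genes), 89.6 percent for E9.5 embryos (11823 genes) and 95.8 percent for yolk sacs (11820 genes), with 11, 11 and 21 false calls. For the interactions the share was 41.3 percent between stages (11120 genes, 13 false calls) and 67.7 percent between tissues (10326 genes, 9 false calls). All genes of a simulated set had the same dispersion, and no difference between replicate numbers or in tissue content was simulated. The E8.5 simulation used union of exon lengths, unlike the real table. The shares therefore test the procedure and do not give the power in the real libraries.

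Replicate numbers are shared by the groups of a set. The numbers were taken to pair libraries where the deviations of every same-numbered pair from the group means correlated above 0.1. In yolk sac the 4 correlations across genes were 0.36, 0.30, 0.39 and 0.21, and the pairing comes from the numbers in the titles. In the embryo sets at least 1 pair fell below that value, so those numbers are not treated as pairs.

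Reads of genes with near-identical copies, such as globins, ribosomal protein genes and their pseudogenes, and Rhox genes, may have been divided between the copies, and their values are uncertain. Mitochondrial tRNA genes are shorter than a sequencing fragment and adjoin other transcripts, so their values are uncertain too. No sequence data were used.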

Results

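Transcripts were measured in 24 libraries, 4 KO and 4 WT in each of 3 sets, at a depth of 15555422 to 23373128 fragments. Per the series' own description, KO embryos resembled their littermates in form at E8.5 and were smaller than them at E9.5, and the comparisons ask how gene expression differs between the genotypes at each stage and in the yolk sac.

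Cmtr2, the targeted gene (ENSMUSG00000046441, GRCm38 chromosome 8, 110215665 to 110224486, plus strand), was lower in KO libraries of all 3 sets. Its scaled FPKM in E8.5 embryos was 6.16 ± 0.395 in WT and 0.704 ± 0.160 in KO (SD, n = 4 each), so KO libraries held 11.4 percent of the WT level. In E9.5 embryos the values were 3.51 ± 0.594 and 0.539 ± 0.126, or 15.4 percent. In yolk sac they were 3.57 ± 0.341 and 0.197 ± 0.0961, or 5.52 percent. The exact two-sided permutation p was 0.0286 in each set, the smallest that 4 against 4 libraries allow. The part of the gene that the allele removes is not given in the sources used here. Cmtr1, the paralogue that methylates the adjacent cap nucleotide, had an FPKM of 1.02 ± 0.383 in WT and 1.20 ± 0.159 in KO at E8.5 (n = 4 each, limma adjusted p = 0.656). It was below the filter in the E9.5 sets, at 0.309 in WT and 0.215 in KO embryos and at 0.190 in both genotypes of yolk sac.

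**Figure D1:**
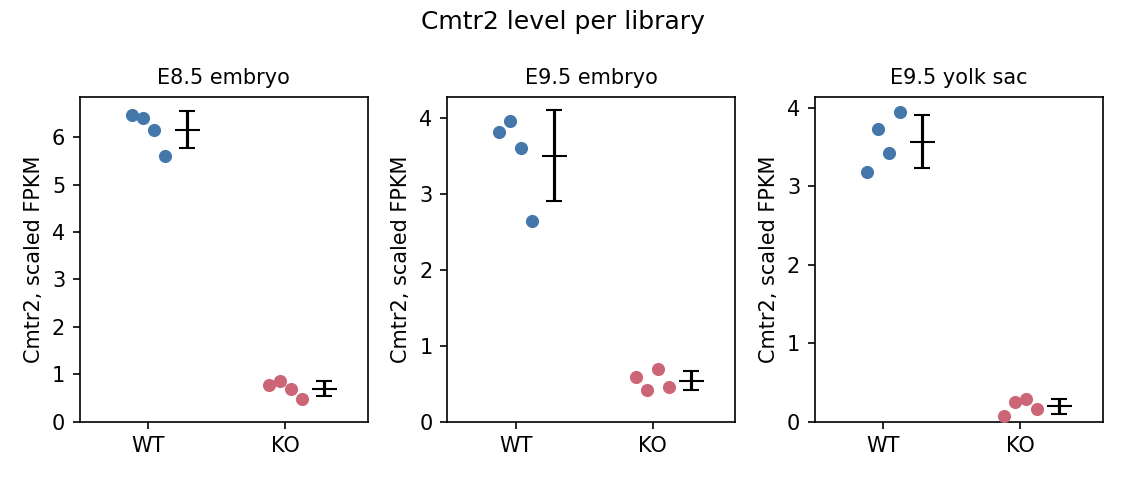
Scaled FPKM of Cmtr2 in each library (points) of WT and KO, with the mean ± SD of 4 libraries (bars), in E8.5 embryos, E9.5 embryos and E9.5 yolk sacs. The KO means are 0.704, 0.539 and 0.197 against WT means of 6.16, 3.51 and 3.57, and no KO library reaches a WT library.

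In E8.5 KO embryos the genes with the largest rises were mostly targets of the transcription factor p53. Phlda3, an inhibitor of Akt signalling, went from an FPKM of 15.7 ± 4.47 to 131 ± 20.9 (SD, n = 4; log2 fold change 3.05, SE 0.21). Ddit4l rose by 2.68, Eda2r, a receptor of the tumour necrosis factor family, by 2.55, and Cdkn1a, the cell cycle inhibitor p21, by 2.49. Ccng1 (cyclin G1) rose by 2.13. Of genes that are not on the p53 list used here, Zfp365 rose by 2.16 and the thiamine transporter gene Slc19a2 by 2.12. Cox6b2, an isoform of a cytochrome c oxidase subunit, rose by 2.09 and is not on that list either. Of the 27 measured p53 targets, 13 rose, 0 fell and 14 were not called. Adjusted over the list alone, 17 rose. The camera adjusted p was 1.84e-14, and 0.00412 with an estimated correlation.

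Besides Cmtr2, the largest falls at E8.5 were of Ahi1, which encodes a protein of the cilium (-1.73, SE 0.25), Dus4l, a dihydrouridine synthase-like gene (-1.49), Gas2 (-1.48) and mitochondrial transcripts. The mitochondrial tRNA genes mt-Ti, mt-Th and mt-Tl1 fell by 2.72, 1.89 and 1.68. Among 13 mitochondrial mRNAs mt-Nd4l (-1.53) and mt-Nd6 (-1.08) fell and 9 fell adjusted over the list alone (adjusted p = 3.35e-07, and adjusted p = 0.952 with an estimated correlation). Dus4l lost its call without WT replicate 1, WT replicate 2 or KO replicate 4, at an adjusted p of up to 0.0780, and Ahi1 without KO replicate 4 (0.0571). Gas2, mt-Ti and mt-Nd6 kept theirs in no more than 2 of the 8 such runs, with adjusted p of up to 0.0914, 0.114 and 0.0914.

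Genes of mitosis had a median log2 fold change of -0.38 at E8.5. None of the 34 was called over all genes, 16 fell adjusted over the list alone, and the list adjusted p was 5.80e-05 (adjusted p = 0.952 with an estimated correlation). Markers of primitive erythroid cells had a median of -0.82, with 0 of 29 called and 4 fallen adjusted over the list alone (5.45e-05, and adjusted p = 0.952 with an estimated correlation). Globin genes made up 0.0141 and 0.0691 percent of fragments in KO replicates 1 and 2, against 0.195 to 0.402 percent in the other libraries. The erythroid median was -1.44 in replicates 1 and 2 alone and -0.15 in replicates 3 and 4 alone. Higher lists were visceral endoderm (median 0.55, 0 of 29 called and 0 adjusted over the list alone, adjusted p = 0.0117) and gut epithelium (0.50, 0 of 18 called and 3 risen adjusted over the list alone, 0.00131). With an estimated correlation their adjusted p = 0.952 and adjusted p = 0.704. The mean FPKM of the visceral endoderm list was 115, 90.5, 276 and 234 in WT replicates 1 to 4. In KO replicates 1 to 4 it was 223, 221, 336 and 476, so WT replicates 3 and 4 lay above KO replicates 1 and 2. The trophoblast list had a median of 0.91 and was not called (camera adjusted p = 0.0760, and adjusted p = 0.952 with an estimated correlation). It was called with FPKM as deposited (0.0465) and with the replicate block (0.0108). Carry-over of such tissues in dissection was not tested. The nuclear-encoded respiratory chain had a median of 0.27 (0 of 56 called, 6 risen adjusted over the list alone, adjusted p = 0.000947, and adjusted p = 0.952 with an estimated correlation). The respiratory chain median was 0.08 in replicates 1 and 2 and 0.31 in replicates 3 and 4. Of 80 ribosomal protein genes Rps10 alone was called (0.86, adjusted p = 0.0404), and 2 rose adjusted over the list alone. The list had an adjusted p of 0.00827 (adjusted p = 0.952 with an estimated correlation), which became 0.0807 when a gene length trend was removed, and Rps10 was not called with any 1 library left out, at adjusted p of up to 0.122. Its median was -0.06 in replicates 1 and 2 and 0.41 in replicates 3 and 4. Of the 30 genes on the interferon response list 9 were tested, and of the 20 on the noncoding snoRNA host list 16 were. None of these was called, also adjusted over the list alone (list adjusted p = 0.844 and 0.763). Of the panel, Afp, Apoa1, Ttr, Hba-x, Hbb-bh1, Hbb-y, Myl7, Tnnt2, T and Hoxb9 were not called, and Ifit1 was below the filter in all 3 sets.

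In all, limma called 125 of 13058 genes in E8.5 embryos, 69 risen and 56 fallen, 83 of them by at least 2-fold. After rescaling to TPM the split was 33 risen and 108 fallen, with the median of all genes at -0.11, and with FPKM as deposited it was 71 and 99. Leaving out WT replicates 1 to 4 gave 35, 38, 79 and 51 genes, and leaving out KO replicates 1 to 4 gave 46, 47, 50 and 34. With replicates 1 and 2 against 3 and 4 as a term limma called 1652 genes, 938 risen and 714 fallen. The count was 97 in replicates 1 and 2 alone and 52 in replicates 3 and 4 alone, and the median of the p53 list was 0.83 and 0.91.

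In E9.5 KO embryos Cdkn1a rose from an FPKM of 2.97 ± 0.293 to 43.2 ± 3.63 (SD, n = 4; log2 fold change 3.66, SE 0.12), and Phlda3, Eda2r and Ccng1 rose by 3.37, 3.11 and 2.56. Of 26 measured p53 targets, 17 rose and 0 fell, and the same number rose adjusted over the list alone. The list adjusted p was 2.20e-13, and 0.0343 with an estimated correlation. The log2 fold change was above 0 for 20 members in replicates 1 and 2 alone and for 23 in replicates 3 and 4 alone.

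Genes of hypoxia and glycolysis rose together at E9.5. Of 33, 25 rose and 0 fell, and 26 rose adjusted over the list alone (adjusted p = 2.14e-13, and adjusted p = 0.0769 with an estimated correlation). Ddit4, an inhibitor of mTORC1 signalling, rose by 2.38 (SE 0.38) and the glucose transporter gene Slc2a3 by 1.48 (SE 0.32). The median of the list was 0.84 in replicates 1 and 2 and 0.91 in replicates 3 and 4. Ndufa4l2, a hypoxia-inducible mitochondrial gene outside the list, rose by 2.74 (SE 0.31).

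At E9.5, of 80 ribosomal protein genes 25 rose, 0 fell and 42 rose adjusted over the list alone (1.40e-12, and adjusted p = 0.592 with an estimated correlation). Examples were Rpl36 (1.05) and Rps27l (1.11), a paralogue of Rps27 that p53 is known to induce. Of 55 nuclear-encoded respiratory chain genes 11 rose, among them Ndufa7 (1.02) and Cox4i1 (0.81), and Ndufs1 fell by 0.56. Adjusted over the list alone 21 rose and 1 fell (1.97e-07, and adjusted p = 0.592 with an estimated correlation). Across genes, which are not independent replicates, the Spearman correlation of gene length with the log2 fold change was -0.36, and risen genes had a median length of 2694 bases against 6780 bases in fallen genes. After quantile normalization the ribosomal median went from 0.52 to 0.14 and that of the respiratory chain from 0.43 to 0.18, with an adjusted p of 0.0370 for each list. With a gene length trend removed the adjusted p was 6.32e-07 for ribosomal proteins and 0.00313 for the respiratory chain, and after quantile normalization and removal of the trend it was 0.834 and 0.909. The ribosomal median was 0.27 in replicates 1 and 2 and 0.67 in replicates 3 and 4, and that of the respiratory chain 0.28 and 0.48. The mitochondrial tRNA genes mt-Ti and mt-Tc rose by 2.40 and 2.34.

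Besides Cmtr2, Pklr, the pyruvate kinase of liver and red cells, fell by 2.20 (SE 0.30) and Ahi1 fell by 1.99. Other fallen genes were Fabp7, a marker of radial glia (-1.76), the homeobox genes Dbx1 (-1.66), Pou3f4 (-1.70) and Nkx2-1 (-1.76), and Lrrn1 (-1.74). Without the 3 libraries low in tail genes (WT replicates 1 and 3 and KO replicate 2) these 5 were not called, with adjusted p from 0.0763 (Lrrn1) to 0.0997 (Nkx2-1) and log2 fold changes from -1.57 (Fabp7) to -1.09 (Pou3f4). Nor were Pklr (-2.04, adjusted p = 0.0642) or Cmtr2 itself (-1.81, 0.0577) in that smaller run, which called 6 of the 35 named genes called with all libraries. The neural progenitor list was not called (adjusted p = 0.152, and 0.789 without those libraries), nor was the neuronal differentiation list (0.0805 and 0.630). The neuronal differentiation list, with a median of -0.44, was called with a gene length trend removed (0.0275) and with the replicate block (0.0450). Of 30 primitive erythroid genes 6 fell, 0 rose and 14 fell adjusted over the list alone (9.36e-07, and adjusted p = 0.638 with an estimated correlation). Rhag, which encodes a red cell membrane protein, fell by 1.75, and the list median was -1.04 in replicates 1 and 2 and -1.24 in replicates 3 and 4. The mean FPKM of the list was highest in a KO library, replicate 4, at 432, against 204 to 367 in WT libraries and 43.3 to 145 in the other KO libraries. Of 34 mitosis genes 9 fell, among them Mki67 (-0.97) and Kif11 (-0.83), and adjusted over the list alone 14 fell and 2 rose. The list adjusted p was 0.0130 (adjusted p = 0.592 with an estimated correlation), with medians of -0.39 in replicates 1 and 2 and -0.22 in replicates 3 and 4. Without the 3 libraries low in tail genes the mitosis list was not called (adjusted p = 0.0583), with a median of -0.36 against -0.33 with all libraries. Of 13 mitochondrial mRNAs 5 fell, including mt-Co1 (-0.96) and mt-Nd4 (-0.84), and 6 fell adjusted over the list alone (0.00834, and adjusted p = 0.638 with an estimated correlation).

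Some E9.5 embryo libraries differed in regional marker genes. T, the brachyury gene of the tailbud, had an FPKM of 0.511 in WT replicate 1, 1.23 in WT replicate 3 and 0.990 in KO replicate 2, against 8.86 to 18.6 in the other 5 libraries. WT replicates 1 and 3 were also low in the cardiac gene Myl7, at 2.58 and 5.16, where the other libraries had 71.3 to 401. Cardiomyocyte genes had a mean log2 fold change of 1.31 (1 of 26 risen, Irx4 at 0.69, and 0 adjusted over the list alone; adjusted p = 0.00166, and adjusted p = 0.748 with an estimated correlation). Tailbud genes had a median of 0.64, and Sp5 (1.00) and Lin28a (0.77) rose, 2 of 14 and also 2 adjusted over the list alone (0.0212, and adjusted p = 0.638 with an estimated correlation). Without those 3 libraries the adjusted p of both lists was 0.351, and the cardiomyocyte median, above 0 with all libraries, was -0.33. Without WT replicate 1 alone the cardiomyocyte and tailbud lists had an adjusted p of 0.0667 and 0.0969, and the tailbud list had 0.0963 when a gene length trend was removed. Of 10 decidua and parietal endoderm genes Fst rose (0.96), also adjusted over the list alone, and the list had an adjusted p of 0.0489 (adjusted p = 0.489 with an estimated correlation). Its median of 0.29 was -0.05 after rescaling to TPM, which moved the median of all genes to -0.34. The list was not called without the 3 libraries (0.341) or without WT replicate 1 (0.101).

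Of the 30 genes on the interferon response list 6 were tested. Of these Bst2 (1.32) and Ifitm3 (1.20) rose, and 2 rose adjusted over the list alone, while the list was not called (adjusted p = 0.510). Among 15 noncoding snoRNA host genes Snhg15 rose by 0.83 and 1 rose adjusted over the list alone (list adjusted p = 0.840). The panel genes Afp, Apoa1, Ttr, Hba-x, Hbb-bh1, Hbb-y, Myl7, Tnnt2, T and Hoxb9 were not called.

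**Figure D2:**
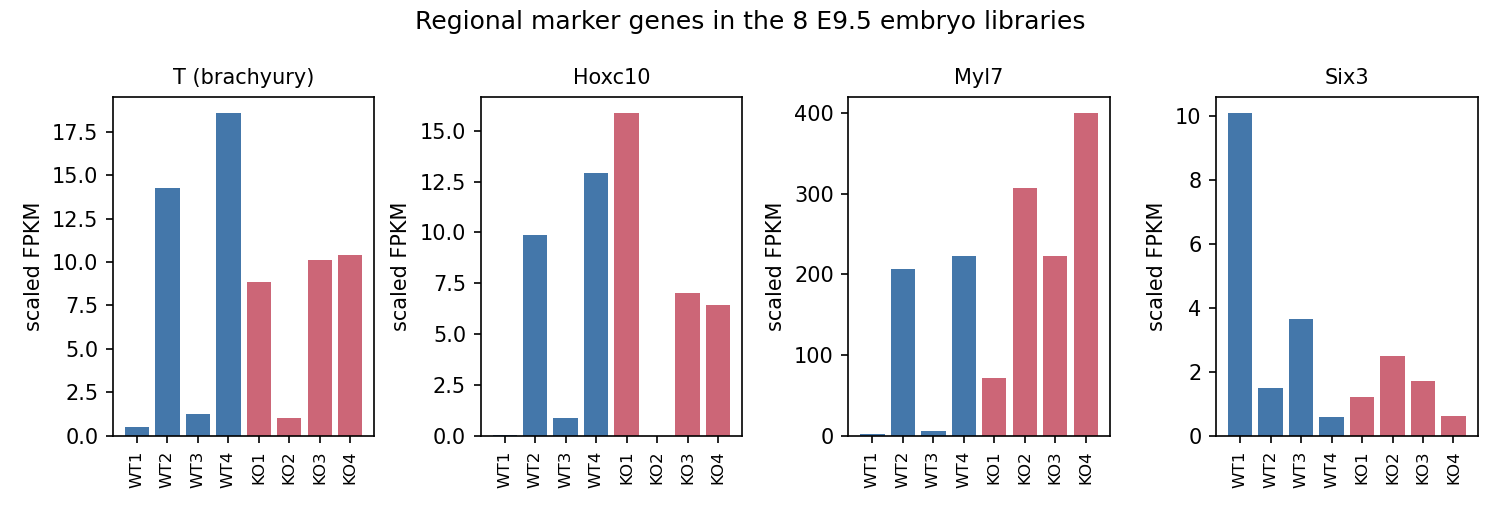
Scaled FPKM of T, Hoxc10, Myl7 and Six3 in each of the 8 E9.5 embryo libraries (bars; WT blue, KO red). T was 0.511, 1.23 and 0.990 in WT replicates 1 and 3 and KO replicate 2, and Six3 was highest in WT replicate 1, at 10.1.

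In all, limma called 1637 of 12027 genes in E9.5 embryos, 884 risen and 753 fallen, 239 of them by at least 2-fold. After rescaling to TPM the split was 132 risen and 3113 fallen, with the median of all genes at -0.34. Leaving out WT replicates 1 to 4 gave 2737, 96, 125 and 581 genes, leaving out KO replicates 2 to 4 gave 208, 266 and 285, and leaving out the 3 libraries low in tail genes gave 36. The count was 11 in replicates 1 and 2 alone and 26 in replicates 3 and 4 alone. Of the 35 named genes that were called, 12 were called with each library left out in turn: Ahi1, Ddit4, Ccng1, Cdkn1a, Rhag, Eda2r, Ndufa4l2, Pklr, Phlda3, Ndufa7, Cmtr2 and mt-Tc. Each of the others lost the call without WT replicate 2 or WT replicate 3, and most also without KO replicates 2 to 4, with adjusted p of up to 0.128 (Irx4).

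In E9.5 KO yolk sacs the arterial connexin genes Gja5 and Gja4 fell. The endothelium list, which holds Gja4, was not called (median 0.08, camera adjusted p = 0.215). Of its 27 measured genes 1 rose and 1 fell, and 2 rose and 2 fell adjusted over the list alone. Gja5 went from an FPKM of 5.17 ± 0.925 to 0.305 ± 0.135 (SD, n = 4; log2 fold change -2.82, SE 0.18) and Gja4 from 4.93 ± 0.965 to 0.979 ± 0.554 (-1.93, SE 0.25). Csf2rb, the shared beta chain of several cytokine receptors, fell by 2.35, Mfsd4b5 by 2.22, the gluconeogenic gene Fbp2 by 1.92 and the Fc receptor gene Fcgr3 by 1.85. The prostaglandin-degrading enzyme gene Hpgd fell by 1.69 and Pklr by 1.61. Fcgr3 lost its call without WT replicate 2 (adjusted p = 0.0524).

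The p53 targets rose in yolk sac as well. Cdkn1a rose by 2.07 (SE 0.16), Eda2r by 1.88, Phlda3 by 1.76 and Bbc3, which encodes the pro-apoptotic protein Puma, by 1.63. Of 27 measured targets 13 rose and 1 fell, and 20 rose and 1 fell adjusted over the list alone (6.66e-13, and 0.0102 with an estimated correlation). The fallen member was Tigar (-0.53), a fructose bisphosphatase that lowers glycolysis. Its call held in 3 of the 8 runs that left out 1 library (adjusted p of up to 0.0857). The list median was 0.59 in replicates 1 and 2 and 0.54 in replicates 3 and 4. Risen genes that are not on the p53 list used here were Cyp26a1, which encodes a retinoic acid-degrading enzyme (2.02, SE 0.40), Psrc1 (1.74), Prss12 (1.64) and Fbxo36 (1.63). Cyp26a1 was called in 2 of the 8 runs that left out 1 library, with adjusted p of up to 0.0936.

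**Figure D3:**
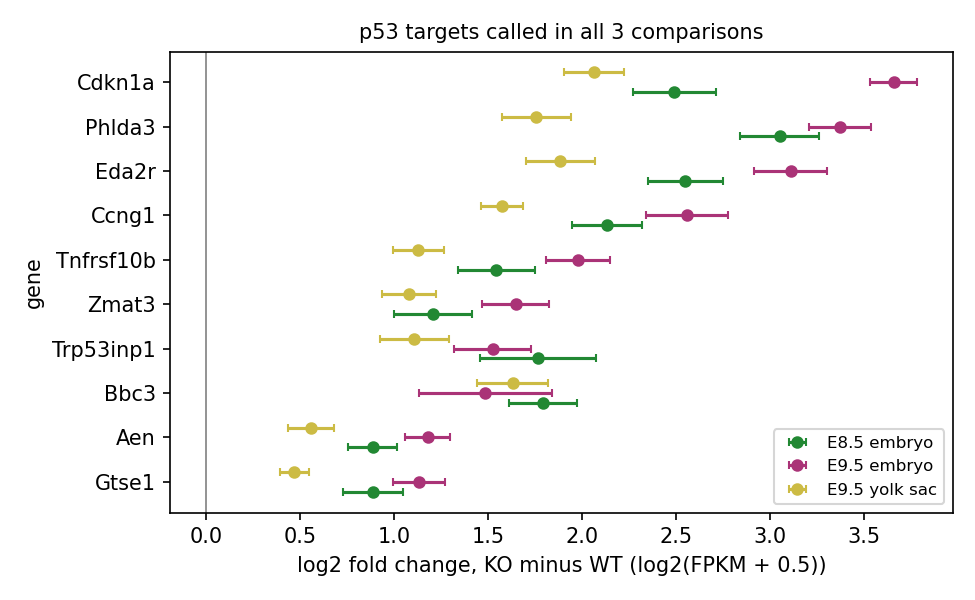
Log2 fold change, KO minus WT, on the log2(FPKM + 0.5) scale, with its standard error (bars), of the 10 genes of the p53 list that were called in all 3 sets. All values lie above 0, and Cdkn1a is at 2.49 in E8.5 embryos, 3.66 in E9.5 embryos and 2.07 in yolk sac.

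Primitive erythroid genes had a median of -0.20 in yolk sac, and Fech, the last enzyme of haem synthesis (-0.97), and Bpgm (-0.79) fell, 2 of 30 and also 2 adjusted over the list alone. Bpgm held in 2 of the 8 runs that left out 1 library (adjusted p of up to 0.0852). The list adjusted p was 0.0329 (adjusted p = 0.882 with an estimated correlation) and 0.0504 with the replicate block, and the median was 0.08 in replicates 1 and 2 and -0.63 in replicates 3 and 4. Of 80 ribosomal protein genes Rps27l rose (0.68, called in 1 of the 8 runs that left out 1 library, adjusted p of up to 0.135) and 0 were called adjusted over the list alone. The list adjusted p was 3.49e-08 (adjusted p = 0.882 with an estimated correlation), with medians of 0.30 in replicates 1 and 2 and 0.18 in replicates 3 and 4. Splicing factor genes had a median of 0.10, with 0 of 34 called, also adjusted over the list alone (0.0441, and adjusted p = 0.882 with an estimated correlation). With FPKM as deposited that list had an adjusted p of 0.0510. None of the 9 interferon response genes tested, of 30 on the list, was called over all genes. Adjusted over the list alone 1 fell, and the list adjusted p was 0.851. Among 14 noncoding snoRNA host genes Snhg15 rose by 0.76, and 1 rose adjusted over the list alone. Snhg15 held in 2 of the 8 runs that left out 1 library (adjusted p of up to 0.0824). That list had an adjusted p of 0.215, and 0.0398 with the replicate block.

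Of 7 trophoblast genes Rhox6 rose (1.38, SE 0.16), and 2 rose adjusted over the list alone (0.00115, and adjusted p = 0.526 with an estimated correlation). Of 10 decidua and parietal endoderm genes 0 were called and 1 rose adjusted over the list alone (0.00109, and adjusted p = 0.882 with an estimated correlation). The mean FPKM of the trophoblast list was 35.3 in KO replicate 2 and 10.2 in KO replicate 1, against 1.68 to 2.77 in WT libraries. It was 3.83 and 4.95 in KO replicates 3 and 4. The mean of the decidua and parietal endoderm list was 170 and 54.6 in KO replicates 2 and 1 and 36.1 and 24.6 in KO replicates 3 and 4, against at most 27.0 in WT libraries. The panel genes Afp, Apoa1, Ttr, Hba-x, Hbb-bh1 and Hbb-y were not called in yolk sac, and Myl7, Tnnt2, T and Hoxb9 were below the filter.

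In all, limma called 341 of 12010 genes in yolk sac, 146 risen and 195 fallen, 88 of them by at least 2-fold. With the replicate block it called 638, 284 risen and 354 fallen, and after rescaling to TPM the split was 87 risen and 192 fallen. Leaving out WT replicates 2 and 4 in turn gave 122 and 89 genes, and leaving out KO replicates 1, 2 and 4 gave 192, 163 and 183. Limma called 0 genes in replicates 1 and 2 alone, where 2112 had an unadjusted p under 0.05, and 2 in replicates 3 and 4 alone, where 1607 did.

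The effect of genotype was compared between stages in the 11595 genes tested in both. Limma found 6 genes whose signed log2 fold change was higher at E9.5 than at E8.5 and 0 in which it was lower, and 572 had an unadjusted p under 0.05. Bnip3, a hypoxia-inducible mitophagy gene, had a log2 fold change of 1.43 at E9.5 and -0.44 at E8.5, a difference of 1.87 (SE 0.21, adjusted p = 0.000732). Ndufa4l2 had 2.74 and -0.41, a difference of 3.15 (SE 0.46), and mt-Ti 2.40 and -2.72, a difference of 5.12 (SE 0.89). The other 3 genes were pseudogenes, named after their values were seen, with the larger change at E8.5. Gm12191 had -0.02 at E9.5 and -2.79 at E8.5, Gm10221 0.32 and -1.53, and Gm4739 0.27 and -1.88. The call of mt-Ti held in 4 of the 16 runs that left out 1 library, with adjusted p of up to 0.139, and leaving out E8.5 WT replicate 3 raised the count to 10. The hypoxia and glycolysis list had a median difference of 0.85 (adjusted p = 3.99e-26, and 0.00213 with an estimated correlation). That of the p53 list was 0.27 (0.0220, and adjusted p = 0.406 with an estimated correlation). Camera also called as higher at E9.5 the ribosomal protein (adjusted p = 1.50e-09), cardiomyocyte (3.02e-06), tailbud (0.00421), anterior Hox (0.0121) and respiratory chain (0.0121) lists. Translation factors (0.0181), posterior Hox genes (0.0203) and DNA replication genes (0.0220) followed. None of these was called with an estimated correlation (adjusted p = 0.805 for each). The E9.5 cardiomyocyte and tailbud calls were lost without the 3 libraries low in tail genes.

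Between tissues at E9.5 the effect differed in 234 of 10511 genes, being higher in yolk sac for 87 and lower for 147. After rescaling to TPM the split was 932 higher and 37 lower, and 45 genes were called with the replicate block. Cdkn1a and Phlda3 rose less in yolk sac than in embryo, by -1.59 (SE 0.20) and -1.61 (SE 0.25), and the stress gene Hmox1 (-1.27) and the glycolytic gene Aldoa (-1.36) also had lower effects. Effects were higher in yolk sac for Sesn3 (1.52), Zfp62 (0.90), Dynlt3 (1.10) and Lgr4 (1.10). Without yolk sac WT replicate 4 Zfp62, Dynlt3 and Lgr4 each had an adjusted p of 0.0530, and Zfp62 had 0.0604 with the replicate block. The median difference was -0.59 for the p53 list (9.02e-05, and 0.0484 with an estimated correlation) and -0.80 for the hypoxia and glycolysis list (3.68e-12, and 0.00405 with an estimated correlation). In these lists 8 and 11 members were called lower. The ATF4, ribosomal protein, respiratory chain and gut epithelium lists were called lower as well. Called higher were primitive erythroid genes (median difference 0.92, camera adjusted p = 0.00572), mitosis (0.32, 0.0123) and sterol synthesis (0.26, 0.0178). None of these other lists was called with an estimated correlation (adjusted p = 0.842 for each). Leaving out single libraries moved the count of 234 to between 7, without yolk sac WT replicate 4, and 1407, without E9.5 embryo WT replicate 1. It was 967 without E9.5 embryo KO replicate 1, 28, 51 and 145 without embryo WT replicates 2 to 4, and 107, 63 and 120 without embryo KO replicates 2 to 4. It was 80 and 58 without yolk sac WT replicates 2 and 3 and 72, 48, 104 and 154 without yolk sac KO replicates 1 to 4.

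The calls of the 3 sets overlapped. E8.5 and E9.5 embryos shared 49 risen and 25 fallen genes, where 5.003 and 3.01 would come from independent lists (hypergeometric p 2.63e-41 and 4.34e-18, over genes that are not independent). E9.5 embryos and yolk sacs shared 56 and 23, against 10.2 and 7.97, and E8.5 embryos and yolk sacs 23 and 5, against 0.736 and 0.670. Across genes, which are not independent replicates, log2 fold changes correlated at a Pearson r of 0.59, 0.29 and 0.32 in these pairs. Of 10407 genes tested in all 3 sets, 22 rose in each, 10 of them on the p53 list, and Cmtr2, Dus4l and Tstd3 fell in each. Independent lists would give 0.0572 and 0.0328. The E9.5 embryo and yolk sac libraries may come from the same conceptuses, so their calls may not be independent.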

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

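The tests that used replicates 1 and 2 against 3 and 4, matching on gene length or removal of its trend, each also after quantile normalization, or the omission of the 3 E9.5 embryo libraries low in tail genes were chosen after the data had been seen, and the splits of the libraries were planned.

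The p53 target list rose in all 3 sets. The lowest of the 6 medians within replicates 1 and 2 or 3 and 4 was 0.54 (SE 0.13), but each number has 1 library of each genotype, so a batch between numbers cancels in KO minus WT and this value decides nothing. Missing body parts in E9.5 embryos would end the call when the 3 libraries low in tail genes are left out, and the adjusted p was then 1.68e-11 (adjusted p = 0.179 with an estimated correlation), with a median of 1.28 against 1.32 with all libraries. A trend with gene length would give the list the same change as other genes of that length, and the members lay above them by a median of 1.21 (SE 0.31) in E9.5 embryos, and by 1.18 (SE 0.32) after quantile normalization. A response to the loss of Cmtr2 stays open as a hypothesis, and whether it comes from the gene itself or from growth differences between the genotypes was not tested.

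The ribosomal protein and nuclear-encoded respiratory chain lists were higher in E9.5 KO embryos, where shorter genes had higher log2 fold changes in general. With the main scaling, members lay above other genes of the same length by a median of 0.33 (SE 0.04) for ribosomal proteins and 0.26 (SE 0.04) for the respiratory chain, and with the trend removed the adjusted p was 6.32e-07 and 0.00313, which argues against the trend as the whole cause. After quantile normalization the medians were -0.03 (SE 0.03) and 0.03 (SE 0.05) and the adjusted p with the trend removed 0.834 and 0.909, so on that scaling these changes cannot be told apart from the length trend, which stays open. Without the 3 libraries low in tail genes the adjusted p was 2.57e-09 and 0.000318, which argues against missing body parts. RNA quality was not measured and stays open, as does an effect of genotype, and neither list was called with an estimated correlation.

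The cardiomyocyte and tailbud lists were higher in E9.5 KO embryos. Without WT replicates 1 and 3 and KO replicate 2, the adjusted p was 0.351 for both lists, and missing body parts in those libraries may account for the calls. For the tailbud list this is partly built in, since the libraries were picked by low T and Hoxc10 and T is on the list. It is partly built in for the cardiomyocyte list too. The mean FPKM of that list was 0.991 and 1.32 in WT replicates 1 and 3, against 6.92 to 34.3 in the other libraries. Leaving those 2 out was bound to raise the WT mean. Fewer libraries also lower the power, although the p53, hypoxia and ribosomal lists stayed called at the preset correlation. With an estimated correlation these lists were not called in that run (camera adjusted p = 0.179, 0.369 and 0.791). How the tissue was dissected is not given in the sources used here.

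Of the 35 splits of the 8 E8.5 libraries into groups of 4, 2 gave at least 125 called genes, the real one included. By that share chance is not excluded for the count of 125. The other split, with 140, parted replicates 1 and 2 from 3 and 4, with both genotypes on each side. With those numbers as a term limma called 1652 genes, and it called 97 and 52 within them. Among the 8 splits that part all same-numbered libraries the highest other gave 2, and with the block 1261 against 0. The numbers are not treated as pairs at E8.5, and 8 splits are too few to exclude chance. For E9.5 embryos 1 of 35 splits, the real one, gave 1637 genes, and the highest other gave 2. That share is the smallest that 35 splits allow, so chance is unlikely but not excluded. Splits that mix the genotypes can suppress calls, so the gap between 2 and 1637 does not add to that share. The count also ran from 96 to 2737 when single libraries were left out. For yolk sac 1 of 35, the real one, gave 341, and the highest other, again replicates 1 and 2 against 3 and 4, gave 184. Among the 8 yolk sac splits that part all 4 pairs the highest other gave 0, and with the block 638 against 0. For the differences, 100 splits were drawn. Between stages 2 of 100, the real one included, gave at least the real 6 genes, the other giving 55 with the E9.5 genotypes kept. Between tissues 3 of 100, the real one included, gave at least the real 234. The highest other there gave 2266, from a split that exchanges the genotypes in 1 tissue and so adds the effects instead of subtracting them. These shares are low. However, a split that mixes the genotypes carries their effect into the spread within groups, which can suppress calls. The draws therefore cannot exclude chance for either count.

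In 7 of 206 groups of 4 libraries 1 library stood apart from the other 3, where chance sets apart about 5 percent of groups. At E8.5 Slc19a2 was 3.38 in WT replicate 4 (others 2.12 to 2.24), and Cmtr1 was 0.446 there (1.15 to 1.24). In E8.5 KO libraries T was 25.2 in replicate 4 (38.2 to 41.1) and mt-Tl1 was 4.17 in replicate 3 (6.02 to 6.39). At E9.5 Ndufa7 was 57.8 in embryo KO replicate 1 (86.4 to 91.1). In embryo KO replicate 2 T was 0.990 (8.86 to 10.4) and Afp was 42.7 (4.66 to 5.02).

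The effect of genotype differed between stages in 6 genes and between tissues in 234. Between stages the differences of Bnip3, Ndufa4l2 and mt-Ti were 1.87, 3.15 and 5.12. Between tissues, yolk sac minus embryo, those of Sesn3, Zfp62, Dynlt3 and Lgr4 were 1.52, 0.90, 1.10 and 1.10, and those of Cdkn1a, Hmox1, Aldoa and Phlda3 were -1.59, -1.27, -1.36 and -1.61.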

How the results depend on the processing

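Voom, protein-coding genes alone, replicates 1 and 2 against 3 and 4, removal of the length trend, list tests after quantile normalization and the omission of the 3 E9.5 embryo libraries low in tail genes were tried after the data had been seen. Cmtr2 stayed at 11.1, 15.9 and 5.48 percent of WT with FPKM as deposited. No called named gene changed sign under any alternative run. Without a filter, which tests more genes, the counts were 25 in E8.5 embryos, 112 in E9.5 embryos, 146 in yolk sac and 107 for the tissue difference. Array weights gave 3498 in E9.5 embryos, 659 in yolk sac, and 13 and 1729 for the stage and tissue differences. A sex covariate gave 46, 2993 and 203. TPM gave 3245 in E9.5 embryos and 969 for the tissue difference. The replicate block gave 1261 in E8.5 embryos, 146 in E9.5 embryos, 638 in yolk sac and 45 for the tissue difference. In yolk sac the block changed the calls of the erythroid and snoRNA host lists, and no other call of a list or named gene there. For the tissue difference it changed the call of Zfp62 and of no other named gene, and lists were not tested with it. In embryos, where the numbers are not treated as pairs, the same-number correlations were 0.31, 0.38, 0.33 and 0.06 at E8.5 and -0.02, -0.06, -0.21 and 0.15 at E9.5, and 4 and 1 of 8 libraries correlated best with their own number. Replicates 1 and 2 against 3 and 4 as a term gave 1652 in E8.5 embryos and 782 in yolk sac. Replicates 1 and 2 alone gave 11 in E9.5 embryos and 0 in yolk sac (2112 at an unadjusted p under 0.05), and replicates 3 and 4 alone gave 52, 26 and 2, with fewer samples. Length trend removal gave 221 in E8.5 and 957 in E9.5 embryos. Without the 3 libraries low in tail genes the counts were 36 in E9.5 embryos and 983 for the tissue difference, and the cardiomyocyte list turned to a lower median (adjusted p = 0.351). For the stage difference the stricter filter gave 3 and FPKM as deposited 10. Leaving out 1 library gave 34 to 79 genes in E8.5 embryos, 96 to 2737 in E9.5 embryos, 89 to 292 in yolk sac, 4 to 10 for the stage difference and 7 to 1407 for the tissue difference. Shared calls fell from 74 to 13 for E8.5 and E9.5 embryos, from 79 to 11 for E9.5 embryos and yolk sac, and from 28 to 9 for E8.5 embryos and yolk sac at an adjusted p of 0.01, and to 36, 19 and 13 at a log2 fold change of at least 1. Of 8, 10 and 6 lists called in E8.5 embryos, E9.5 embryos and yolk sac, 1 each was called with an estimated correlation. Fry called 1, 9 and 3 lists, not all of which camera had called. In yolk sac these were the p53, trophoblast and tailbud lists (fry adjusted p = 5.54e-05, 0.0448 and 0.0448), and camera did not call the last (0.0545). In E9.5 embryos they included ribosomal proteins (0.0338) but not cardiomyocytes (0.335) or primitive erythroid genes (0.135). Where construction does not show it, the cause was not tested. Depth limits low genes most: genes under an FPKM of 1 in 5 or more libraries were not tested.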

Other observations

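The test of genes near Cmtr2 and the omission of libraries were chosen after the data had been seen, as were the genes named here outside the lists, and the prediction for the stage axis was written before its result was seen.

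Among the 22 genes that rose in all 3 sets, 12 were outside the p53 list. Cox6b2 rose by 2.09, 2.32 and 1.49 in E8.5 embryos, E9.5 embryos and yolk sacs, Scamp5 by 1.26, 1.13 and 0.96, and Fbxo36 by 1.18, 1.74 and 1.63. Serpine2, which encodes an inhibitor of serine proteases, rose by 1.18, 1.73 and 0.92, and Sulf2, a sulfatase of heparan sulfate, by 1.14, 0.82 and 0.94. The mitochondrial protease gene Parl rose by 1.12, 1.15 and 0.77, and the peroxisome gene Pex6 by 1.17, 0.95 and 0.63. Tstd3 fell in each set (-1.02, -1.07 and -0.88).

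Other E9.5 embryo lists that were not called held called members. In the gut epithelium list (adjusted p = 0.0586) the keratin genes Krt8, Krt18 and Krt19 rose by 1.27, 1.21 and 1.71, 6 members rose and 1 fell, also 6 risen and 2 fallen adjusted over the list alone. In the sterol synthesis list (adjusted p = 0.146) Idi1 and Hmgcs1 fell by 1.05 and 1.00, and 4 of 23 members fell, 5 adjusted over the list alone. Among neural progenitor genes (adjusted p = 0.152) Pax6 and Nes fell by 1.01 and 0.94 while En1 rose by 1.04, with 2 of 27 risen and 5 fallen, and 3 and 5 adjusted over the list alone. Without the 3 libraries low in tail genes 4 lists were called that were not called with all libraries, none of them with an estimated correlation (adjusted p = 0.791 for each). The visceral endoderm list turned from a median of 0.61 (adjusted p = 0.146) to -0.94 (0.000599), and without WT replicate 1 alone it had 0.19 (0.568). Of the WT libraries kept, replicate 2 had a mean FPKM of the list of 18.4. Replicate 4 had 7.16, within the 4.61 to 8.87 of KO replicates 1, 3 and 4. Sterol synthesis went from -0.17 to -0.28 (0.0177, and 0.0753 without WT replicate 1) and somites from -0.26 (0.166) to -0.47 (0.0177, and 0.0297 without WT replicate 1). ATF4 and amino acid stress went from 0.10 (0.0692) to 0.27 (0.0150, and 0.0391 without WT replicate 1). Of the imprinted genes Phlda2 rose by 1.87 in embryos (list adjusted p = 0.569) and Cdkn1c by 1.07 in yolk sac (0.345), where Apoa4, a visceral endoderm gene, fell by 1.42.

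Per library, E9.5 embryo WT replicate 4 held 0.273 FPKM of Xist and 0 of the Y-linked genes, while each other E9.5 embryo library held at least 16.1 of Xist or 1.97 of the Y-linked genes. Hoxc10 was 0.0295, 0.877 and 0 in WT replicates 1 and 3 and KO replicate 2.

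A developmental delay was tested by placing the E9.5 embryo libraries on a stage axis. The axis ran from the E8.5 WT mean to the mean of all 8 E9.5 embryo libraries, in fragments recovered from the FPKM of 11591 genes. Its ends come from different tables, so differences between the tables cannot be told apart from stage along it. KO libraries lay at -0.0111 relative to WT libraries (exact two-sided permutation p = 0.914, 4 against 4), and a delay cannot be told apart from none at this size. The sign rests on single libraries: the difference was 0.0558 without WT replicate 1, 0.0310 without WT replicate 3 and 0.0238 without KO replicate 4, and between -0.0711 and -0.00233 without any 1 of the others, with exact permutation p from 0.457 to 0.971. Without the 3 libraries low in tail genes it was 0.144 (exact permutation p = 0.2), where the 10 possible splits cannot give a p under 0.05. A linked or local effect of the Cmtr2 allele was tested in genes within 10 Mb of it. At E9.5 15 of 134 embryo genes there were called, against 1620 of 11888 elsewhere, with 1 of 145 in E8.5 embryos and 5 of 145 in yolk sac. The smallest of the 3 Fisher's exact p-values was 0.525 before adjustment and 0.914 after Benjamini-Hochberg adjustment, and such an effect stays open.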
